A study of Homo sapiens with 6 samples.

How the data were processed

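RNA abundance was measured on 6 one-colour NimbleGen expression arrays, 1 array for each sample of KYSE30, an established human cell line from an esophageal squamous cell carcinoma. According to the titles, 3 samples received a negative control siRNA (siControl, samples 1, 2 and 3) and 3 received an siRNA against MTA2 (siMTA2, samples 4, 5 and 6). Per the labels' protocols, cells were transfected by lipofection at a stated siRNA dose of 20 nmol/ml for 48 h, total RNA was treated with DNase on the column, double-stranded cDNA was labelled with Cy3, and the arrays were scanned on a GenePix 4000B. The labels do not say whether the 3 samples of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. No slide, scan date or other batch was stated, and no replicate number is shared between the groups.

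The deposited values were taken as log2 intensities from their range of -0.83 to 16.00, which ends at the top of a 16 bit scale, since no source used here states the scale. Both deposited tables hold 34558 features and the same values, with a largest difference of 0. The 6 arrays had nearly one distribution as deposited. Medians lay between 10.44 and 10.45 and 25th percentiles between 9.32 and 9.33, whereas the lowest values still differed, with 1st percentiles between 4.79 and 6.57. The background correction, the normalization method and any filter are not given in the sources used here. There are no detection calls, so whether a feature lay above background is unknown. Precision is limited by the number of arrays, 3 per group.

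Each feature carries 1 transcript accession and 1 gene symbol in the deposited table. Symbols were brought up to date through gene numbers (32472 features, from the platform's gene table) or accessions (1337 features) against the gene table of assembly GRCh38.p14. Another 749 features kept the symbol of the file. The platform's gene table listed no feature with several symbols, and 2086 features had no row in it. The features covered 19188 genes, of which 7426 had at least 2 features. The files name no genome build and no probe sequence, so no coordinates are given. Cross-hybridization between near-identical genes, such as members of the IFITM, MT1, PABPC and POTE families, was not tested, and values of such genes are uncertain.

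All features were tested with no further normalization and no filter on dim features. The siMTA2 group was compared with the siControl group by lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, over the 6 arrays, with Benjamini-Hochberg adjustment over 34558 features and a threshold of 0.05. Every log2 difference is siMTA2 minus siControl. For MTA2 an exact two-sided permutation test over the assignments of 3 samples against 3 was added, whose smallest possible p is 0.1. Gene-level results use 1 feature per gene, the one with the highest mean over the 6 arrays. The 24 gene lists (pathways, complexes, cell state genes and markers of other cell types) were tested with camera at a preset inter-gene correlation of 0.01, with MTA2 left out of the NuRD list. Adjustment was over the 24 lists. An estimated correlation and fry were alternatives. The design, the alternatives, the lists and the rule for named genes were fixed before the data were examined.

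Genes named in the text are MTA2 and every measured NuRD subunit, the 15 genes in each direction of largest change past the threshold, and members of each list. Past the threshold the 3 siMTA2 and the 3 siControl values also had to lie apart. Where fewer than 15 passed, places were filled by the smallest unadjusted p among genes with a mean above the 50th percentile. Features without a symbol or with several, and symbols of uncharacterized loci and olfactory receptors, were left out. For each list up to 4 passing members, or the 2 of smallest p where none passed, were named. A result that this rule would name is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

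The fit was tested on simulated data made from the real feature means and the arrays' own residuals, with 200 of 34558 features changed by a known fold. At 2-fold 0% of the changed features were recovered, at 4-fold 31% and at 8-fold 82.5%. Unchanged features had a group difference of 0 by construction there, so false calls could not occur. The residuals were also scaled up, which made the variances larger than in the real data. With independent noise in place of the arrays' residuals, 0%, 58% and 86.5% were recovered, with 1, 5 and 9 false calls. For the lists, run on 19188 genes with the arrays' residuals, a shift of 0.5 on the log2 scale given to each list in turn was called in 24 of 24 lists. All other genes had a group difference of 0 by construction there. The outcome therefore does not show that such a shift would be found in the real data.

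Alternatives were the second deposited table, quantile normalization, a shift of the arrays to one median, filters at the 25th and 50th percentile of mean intensity, a trended and robust variance, array weights, an ordinary t-test, other thresholds, other ways of joining the features of a gene, and leaving out each sample. After seeing the data, 4 were added. These were a covariate from the first axis of the residuals, a block separating arrays 1, 3 and 5 from arrays 2, 4 and 6, leaving out arrays 2 and 5, and leaving out features with a value under 5 on any array. Figures were drawn with matplotlib 3.10.9.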

Results

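The study asked how gene expression in KYSE30 cells differs after an siRNA against MTA2. MTA2 is a subunit of NuRD, a complex that joins histone deacetylase and nucleosome remodelling activity. The siRNA against MTA2 had the sense strand GGUGGGAGAUUACGUCUAUTT. The control siRNA had the sense strand UUCUCCGAACGUGUCACGUTT. Log2 intensities of 34558 features were available for 3 arrays labelled siControl and 3 labelled siMTA2. The median SD between the arrays of one label was 0.275 for siControl and 0.289 for siMTA2. Since the target gene was not lower in the samples labelled siMTA2, as described next, groups are named here by their labels, and every direction rests on those labels.

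MTA2 itself did not differ detectably between the labelled groups. Its single feature (NM_004739) read 12.920, 13.126 and 13.004 in siControl samples 1, 2 and 3. In siMTA2 samples 4, 5 and 6 it read 13.118, 13.178 and 13.524. The group means were 13.02 ± 0.10 and 13.27 ± 0.22 (SD, n = 3 each), a log2 difference of 0.26 with a standard error of 0.19. The 95% interval ran from -0.20 to 0.71, that is from 0.870-fold to 1.64-fold. By limma the adjusted p was 0.967, and the exact two-sided permutation p was 0.2, where 0.1 is the smallest that 3 against 3 samples allow. Where the feature lies on the transcript relative to the siRNA site is not known from the files. Leaving out 1 sample moved the difference to between 0.13 (without sample 6) and 0.33 (without sample 4).

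None of the other 14 NuRD subunit genes passed the test either. CHD5 and CHD3, remodelling ATPases of the complex, had the smallest p-values. CHD5 read 9.21 ± 0.16 against 9.68 ± 0.18, a log2 difference of 0.47 (standard error 0.19). CHD3 read 9.83 ± 0.10 against 9.04 ± 0.67, a difference of -0.79 (standard error 0.33), and both had an adjusted p of 0.967. The deacetylases HDAC1 and HDAC2 had differences of -0.17 and -0.0048. The main ATPase CHD4 differed by -0.02, and the scaffold paralogs MTA1 and MTA3 by 0.20 and -0.15. The methyl-CpG-binding proteins MBD2 and MBD3 differed by 0.46 and 0.32, and the histone chaperones RBBP4 and RBBP7 by 0.30 and -0.04. CDK2AP1 differed by -0.33 and GATAD2A by -0.15. GATAD2B differed by -1.61 with a standard error of 0.75, which became -0.69 without sample 4, and its siMTA2 values had an SD of 1.60, with a value under 5 on at least 1 array. Without MTA2 the list had a mean difference of -0.11, which rested on GATAD2B and was 0.0065 over the other 13 genes, with a median of -0.03, 5 members higher and 9 lower. It was not called (camera adjusted p = 0.959, and adjusted p = 0.960 with an estimated correlation). Leaving out 1 sample moved 13 of the 15 NuRD genes, MTA2 included and CHD5 and RBBP4 excepted, by over 1.5 times, and turned the signs of HDAC2, MTA3, RBBP7, CHD4 and GATAD2A. The difference of MBD2 ranged from 0.16 without sample 3 to 0.67 without sample 5, and that of CHD3 from -1.02 without sample 4 to -0.41 without sample 6.

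**Figure D1:**
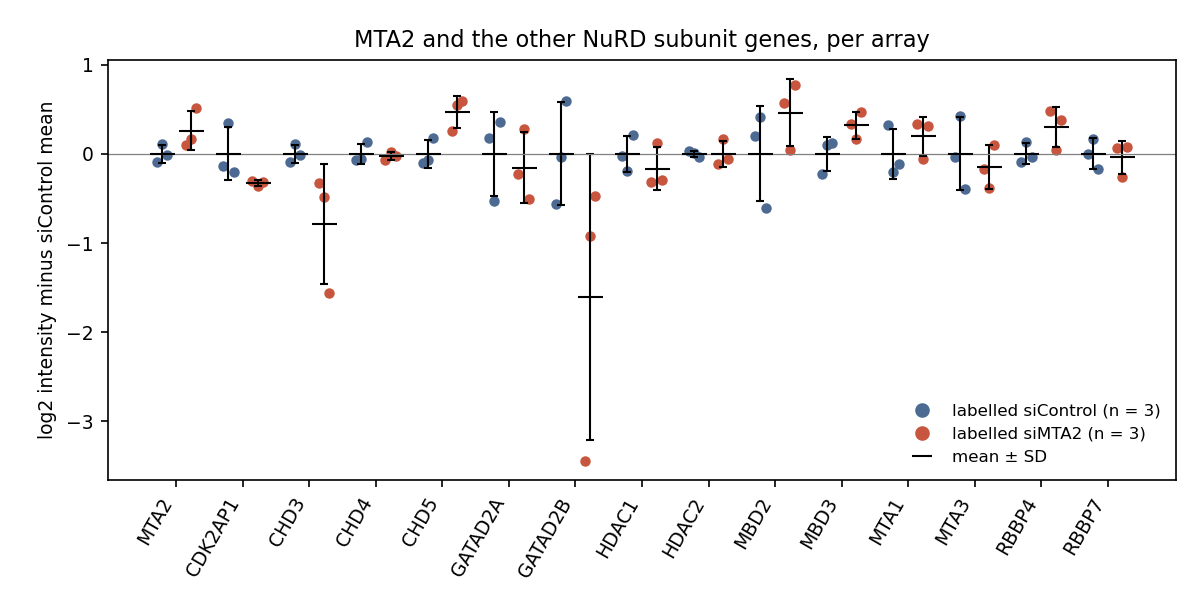
Log2 intensity of MTA2 and the other NuRD subunit genes minus the siControl mean of each gene, with 1 point per array, colours for the labelled groups, and black bars for the mean ± SD (n = 3). MTA2 lies 0.26 higher in the samples labelled siMTA2, and the widest spread is that of GATAD2B, whose siMTA2 SD is 1.60.

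Across the whole array, 0 of 34558 features differed between the labelled groups at an adjusted p under 0.05 by limma. At an unadjusted p under 0.05 there were 1268 features, 595 higher and 673 lower in siMTA2, where 1728 would be expected with no difference at all. Features vary together across the arrays, and the other splits of the 6 arrays into 3 and 3 gave 637 to 6661. A count under 1728 therefore does not show that nothing differs. With an added fold of at least 1.5 there were 933 features (402 higher, 531 lower), and with a fold of at least 2 there were 234 (95 higher, 139 lower). With each feature's own variance in place of limma's moderated one, 0 features passed after adjustment and 1375 had an unadjusted p under 0.05, 831 higher and 544 lower. The side with more features turned with single samples too, with 974 higher and 705 lower without sample 2, 780 and 540 without sample 3, and 399 and 376 without sample 1. Without sample 5 it did not turn, with 884 higher and 1495 lower. Groups did not overlap in 3053 features (8.83%), against 10% by chance, a share with the same limit. Leaving out sample 1 gave 775 features at an unadjusted p under 0.05, leaving out sample 6 gave 758, and leaving out sample 5 gave 2379.

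No gene with higher signal in siMTA2 passed the test, so the following are the 15 of smallest unadjusted p, each with an adjusted limma p of 0.967. SPINK5, a serine protease inhibitor of the cornifying epithelium, read 11.64 ± 0.43 against 12.85 ± 0.27, a log2 difference of 1.21 (standard error 0.27). SLURP1, a secreted Ly6 family protein, differed by 0.60 and the aminopeptidase XPNPEP2 by 0.65. IFITM3, which restricts virus entry, read 10.42 ± 0.03 against 11.22 ± 0.12, a difference of 0.79 (standard error 0.17). The metallothionein gene MT1E differed by 0.71. IFITM3, MT1E, PABPC3 and POTEJ have near-identical relatives, and their values are uncertain for that reason. PABPC3, a poly(A)-binding protein gene, read 11.41 ± 0.13 against 12.33 ± 0.21, a difference of 0.92. The nucleoporin NUP155 differed by 0.76, the zinc finger gene ZNF609 by 0.84 and the radial spoke gene RSPH9 by 1.07. TVP23C differed by 1.04, GTF2A1L by 0.74, KCNG2 by 0.71, HTATIP2 by 0.70, POTEJ by 0.68 and ZFR2 by 0.61.

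On the lower side none passed either, and the 15 genes of smallest p again had adjusted limma p-values of 0.967. HPRT1, a purine salvage enzyme often used as a reference gene, read 12.18 ± 0.11 in siControl and 10.75 ± 0.50 in siMTA2, a log2 difference of -1.44 (standard error 0.28). VCL, which encodes vinculin, differed by -0.76 and the profilin gene PFN2 by -0.80. UBE2E3, a ubiquitin-conjugating enzyme, read 13.36 ± 0.40 against 12.13 ± 0.23, a difference of -1.23. MACROH2A1, which encodes a histone variant, differed by -1.14 (standard error 0.30). The fructose transporter gene SLC2A5 differed by -0.96, the 14-3-3 gene YWHAB by -0.79 and the ribosome assembly gene PNO1 by -1.15. OLA1 differed by -1.25, PRR19 by -1.21, SEC16B by -1.19 and MAB21L1 by -1.03. CLTCL1, a clathrin heavy chain gene, differed by -0.99, OCIAD2 by -0.86 and FADS3 by -0.83. All 30 genes kept their direction under each alternative run on them. The labelled groups did not overlap for any of these genes, so leaving out samples, array weights or the block could not turn a sign.

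The lowest adjusted limma p of any feature, 0.0951, belonged to EIF4E, which encodes the cap-binding translation factor and was singled out after its values were seen. That feature (NM_001130679) read -0.22 ± 0.16 in siControl and 5.69 ± 0.97 in siMTA2, a fitted log2 difference of 5.92. Its control values of -0.40, -0.16 and -0.10 lay at the bottom of the scale. The feature was past the threshold in 2 of the 6 fits that left out 1 sample, with adjusted limma p-values of 0.0258 without sample 4 and 0.0355 without sample 6. A second EIF4E feature (NM_001130678) read 0.85, 6.34 and 0.37 in siControl and 4.81, 5.57 and 5.85 in siMTA2. The third (NM_001968), the brightest of them, also lay near the bottom of the scale, with 4.33 in sample 1. It differed by 0.73 with a standard error of 0.67. In the list of cap-dependent translation initiation genes, 0 of 17 members passed, and the list was not called (mean difference 0.05, camera adjusted p = 0.959). EIF4EBP1, the repressor of EIF4E, differed by -0.53 (standard error 0.18) and the helicase cofactor EIF4H by 0.51 (standard error 0.20).

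Among the 24 gene lists fixed in advance, 0 were called by camera. The lowest adjusted p was 0.848 at the preset correlation, and the lowest adjusted p was 0.960 with an estimated correlation. Mean differences of the lists ran from -0.11 to 0.21 on the log2 scale, and from -0.07 to 0.16 with the member farthest from 0 left out of each list. Without that member the means of the NuRD, p53, apoptosis, interferon and leukocyte lists turned sign. Over all 660 genes in the lists, 0 passed when adjusted over all features, 0 passed when adjusted over the list alone, and 23 had an unadjusted p under 0.05. In simulated data a shift of 0.5 was called in each of the 24 lists. All other genes had a group difference of 0 there, so it is not known which shift would be called in the real data.

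**Figure D2:**
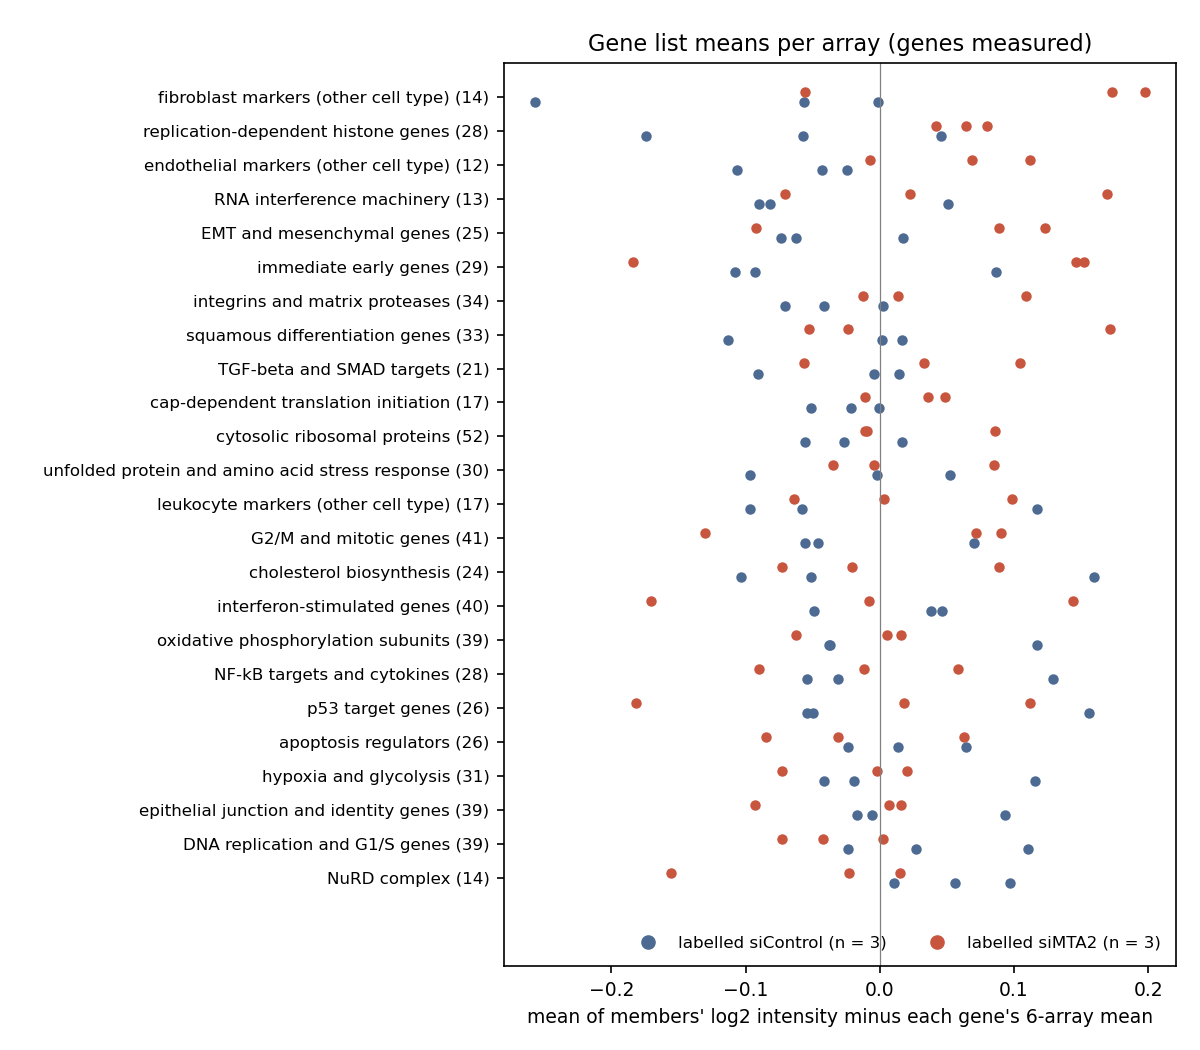
Mean over the members of each gene list of the log2 intensity minus each gene's mean over the 6 arrays, with 1 point per array and the number of genes measured in brackets. List means differ between the labelled groups by -0.11 to 0.21, where the lowest mean, that of the NuRD list, rests on GATAD2B.

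No list of genes of cell identity or invasion passed the test. In the list of genes of epithelial-mesenchymal transition, 14 of 25 members were higher and 11 lower (mean difference 0.08, camera adjusted p = 0.959). POSTN, a matrix protein of mesenchymal cells, read 7.34 ± 0.24 against 8.47 ± 0.54, a difference of 1.13 (standard error 0.30), and the mesenchymal cadherin gene CDH11 differed by 0.88 (standard error 0.37). Of 39 epithelial junction and identity genes, 18 were higher and 21 lower (mean difference -0.05, camera adjusted p = 0.860). The desmosomal cadherin gene DSC3 differed by -0.66 and the tight junction gene CLDN1 by 0.70 in that list. Squamous differentiation genes had 17 members higher and 16 lower (adjusted p = 0.959). There S100A8 differed by -0.54 and the esophageal keratin gene KRT4 by 0.68, which became -0.33 for S100A8 without sample 4 and 0.35 for KRT4 without sample 2. Integrins and matrix proteases had 23 of 34 members higher (mean difference 0.07, camera adjusted p = 0.848), with ITGB6 at 0.49 and ITGA2 at 0.45. By fry that list had an unadjusted p of 0.0382 and an adjusted p of 0.865. TGF-beta and SMAD targets had 10 members higher and 11 lower (adjusted p = 0.959), with the basement membrane collagen gene COL4A1 at 0.60 and CCN1 at 0.97.

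No list of proliferation or survival genes passed the test. DNA replication and G1/S genes had 23 of 39 members lower (mean difference -0.08). This was the only list with an unadjusted camera p under 0.05 (0.0391), and its adjusted p was 0.848, with an adjusted p of 0.960 with an estimated correlation. RRM1, the large subunit of ribonucleotide reductase, read 11.86 ± 0.22 against 11.12 ± 0.18, a difference of -0.74 (standard error 0.20), and the sliding clamp gene PCNA differed by -0.36 (standard error 0.17). Of 41 G2/M and mitotic genes 24 were higher and 17 lower (adjusted p = 0.959), with the spindle checkpoint gene MAD2L1 at -0.61 and NUSAP1 at -0.57. The p53 targets had 15 of 26 members higher, with a mean difference of -0.03 (adjusted p = 0.959). Among them RRM2B differed by -1.16 and SESN2 by -0.74. Apoptosis regulators also had 15 of 26 members higher (mean difference -0.04, adjusted p = 0.871). Its members of smallest p were the pore-forming BAK1 at -1.15 (standard error 0.32) and the death receptor adaptor FADD at -0.83 (standard error 0.26).

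Genes of innate and stress responses showed no shift that passed the test. Interferon-stimulated genes had 21 of 40 members higher, with a mean difference of -0.02 (camera adjusted p = 0.959). IFITM3 had the smallest p in that list (limma, adjusted p = 0.0940, adjusted over the list alone), while MX1 differed by -0.48. The member farthest from 0 was IFITM2, of the same family as IFITM3 and named after its values were seen. It differed by -1.30, the opposite direction to IFITM3, and the list mean without it was 0.0093. NF-kB targets and cytokines had 15 of 28 members higher and a mean difference of -0.03 (adjusted p = 0.959), with the adhesion receptor gene ICAM1 at -0.54 and the chemokine gene CCL5 at -0.41. Immediate early genes had 17 of 29 members higher (adjusted p = 0.959), with JUN at 0.79 and DUSP5 at -0.50. Genes of the unfolded protein and amino acid stress response had 19 of 30 members higher (adjusted p = 0.959), with SESN2 at -0.74 and the pseudokinase gene TRIB3 at 0.47. The RNA interference machinery, with 10 of 13 measured members higher, was not called (adjusted p = 0.959), and its members of smallest p were TNRC6A at 0.33 and TNRC6C at -0.30.

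No metabolic or housekeeping list passed the test. Cholesterol biosynthesis genes had 12 members higher and 12 lower (adjusted p = 0.959), with the squalene synthase gene FDFT1 at -0.64 and MVK at -0.41. In the hypoxia and glycolysis list 16 of 31 members were higher (adjusted p = 0.959), with the glucose transporter gene SLC2A1 at -0.64 and NDRG1 at -0.44. Oxidative phosphorylation subunits had 18 higher and 21 lower (adjusted p = 0.860), with NDUFV2 at -0.53 and COX5A at -0.48. Of 52 cytosolic ribosomal protein genes 34 were higher (mean difference 0.04, adjusted p = 0.959), with RPL3 at -0.45. Replication-dependent histone genes had 17 of 28 members higher (mean difference 0.12, adjusted p = 0.848), with H1-3 at -0.49 and H2AC11 at 0.61. In 8 of the 24 lists the median, the mean and the test direction did not share a sign. These were the squamous, p53, apoptosis, interferon, NF-kB, hypoxia, TGF-beta and leukocyte lists.

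Markers of other cell types were included to see whether the make-up of the samples differed between the labelled groups. Fibroblast markers had a mean difference of 0.21 (0.14 without the member farthest from 0), with 10 of 14 members higher (camera adjusted p = 0.848), and FBLN1 at 0.50 and PRRX1 at 0.84. PRRX1 ranged from 0.29 without sample 2 to 1.32 without sample 3. Endothelial markers had 10 of 12 members higher (mean difference 0.12, adjusted p = 0.848), with PECAM1 at -0.36 and CDH5 at 0.25. Leukocyte markers had 11 of 17 members higher (mean difference 0.02, adjusted p = 0.959), with CD3E at -0.77 and LYZ at -0.55. No marker in these lists passed the test, which compares the labelled groups and does not show whether such cells were absent. Percentiles of mean intensity among all features were 73.1 for CD3E, 75.1 for PECAM1, 71.4 for FBLN1 and 62.5 for CDH5. They were 27.3 for PRRX1 and 11.2 for LYZ. Without detection calls, these levels cannot tell whether the markers were expressed.

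Arrays did not resemble one another by label. Spearman correlations over all features ran from 0.937 to 0.971 between arrays of the same label and from 0.927 to 0.975 between arrays of different labels. The highest was that of siControl sample 3 with siMTA2 sample 5. The first principal component, with 38.8% of the variance, placed samples 1, 3 and 5 at -67.4, -50.3 and -36.8, and samples 2, 4 and 6 at 41.4, 57.7 and 55.3. Each side thus held samples of both labels. With these sides as a block in the fit, 0 features passed and MTA2 differed by 0.21. With the first residual axis as a covariate, 1 feature passed, ARL6IP6, named after its values were seen, whose lowest value was -0.56. Both fits were chosen after seeing the data. The residual axis was taken from the residuals of the same fit, so p-values with it tend to be too small.

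**Figure D3:**
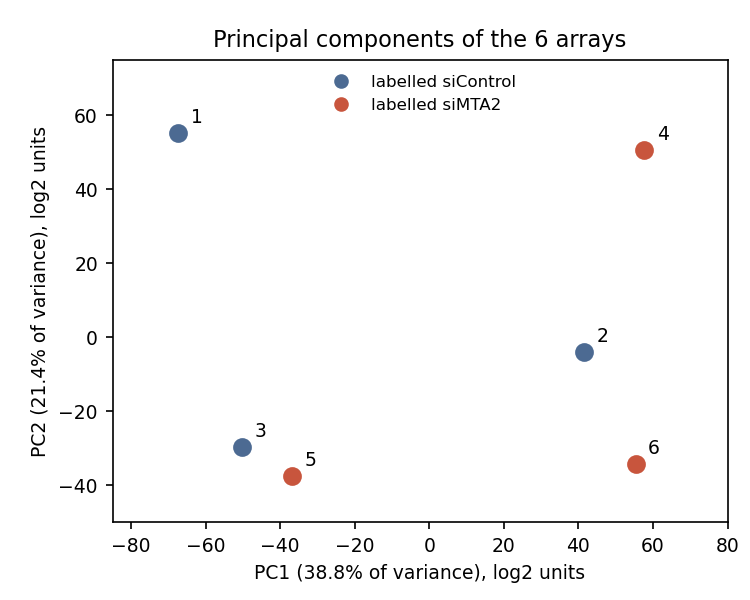
Scores of the 6 arrays on the first and second principal components of all 34558 features, in log2 units, with the sample number beside each point and colours for the labelled groups. Samples 1, 3 and 5 lie left of 0 and samples 2, 4 and 6 right of it, so each side holds both labels.

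**Figure D4:**
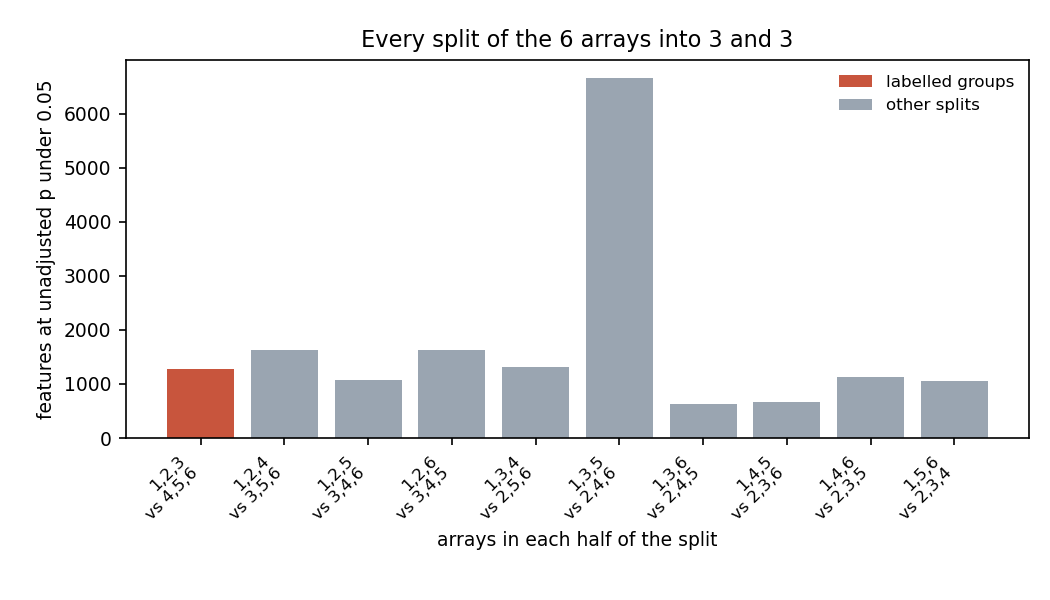
Number of features at an unadjusted p under 0.05 for each of the 10 splits of the 6 arrays into 3 and 3, with the labelled groups in red. The labelled groups give 1268 features and the split of samples 1, 3 and 5 against 2, 4 and 6 gives 6661.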

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

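Chosen after the data were seen were the residual axis, the block, and leaving out arrays 2 and 5 or features with a value under 5. The count of 0 features at an adjusted p under 0.05 stayed at 0 under the second deposited table (identical values), quantile normalization, the shift to one median, the trended and robust variance, array weights, both filters on dim features, the ordinary t-test and both ways of joining the features of a gene. The threshold of 0.01 and the test against a fold of 1.2 are stricter by construction and could only give 0. Leaving out 1 sample gave 0 to 4 features. These were ARL6, EHBP1L1, ADAM29 and POTEB2 without sample 2, EIF4E without sample 4, and EIF4E and LOC391322 without sample 6, named after their values were seen, and each has a value under 5 on at least 1 array. Replacing the adjustment by an unadjusted p with a fold of at least 1.5 or 2 gave 933 and 234 features, by construction a looser rule. The residual axis gave 1 feature, and the block and the removal of features with such values gave 0. Leaving out arrays 2 and 5 leaves samples 1 and 3 against 4 and 6, which are also the opposite sides of the first principal component, so this fit cannot tell the labels from that axis. It gave 18 features, of which 9 have a value under 5, and 4536 at an unadjusted p under 0.05. The count of 1268 features at an unadjusted p under 0.05 became 2743 with array weights and 2179 with the residual axis, where the cause was not tested. It became 595 above the 50th percentile, 719 with features averaged per gene and 720 with 1 feature per gene, where fewer features were tested. The share of higher features among them ran from 37.2% without sample 5 to 60.4% with the ordinary t-test. Leaving out 1 sample gave 758 (sample 6) to 2379 (sample 5), with 775 without sample 1. The count of 0 gene lists did not change under any alternative run on lists. No list mean changed sign with quantile normalization or the shift to one median, which hardly move most values. MTA2 kept its sign and stayed short of the threshold under each, with differences from 0.13 without sample 6 to 0.36 without arrays 2 and 5. Of 1247 values of the 89 named genes under alternatives, 1233 kept their direction and their side of the threshold and 14 turned sign, all in 5 NuRD genes. Many of these values could not turn, as the second table, the trended and robust variance and the residual axis leave every difference unchanged. Genes whose groups do not overlap cannot turn sign when samples are left out. Leaving out 1 sample moved 31 of the 89 by over 1.5 times, 13 NuRD genes and CDH11, CLDN1, S100A8, KRT4, MX1, ITGA2, FDFT1, MVK, NDRG1, JUN, CCN1, H2AC11, TNRC6C, PRRX1, CD3E, LYZ, PECAM1 and CDH5. NuRD genes were named whatever their values, some near 0, and the others for small p here, so these counts cannot compare their stability. Without 1 sample HDAC2 ranged from -0.088 to 0.050, MTA3 from -0.34 to 0.064, RBBP7 from -0.13 to 0.066, CHD4 from -0.059 to 0.039 and GATAD2A from -0.42 to 0.025. With the block HDAC2 was 0.036, CHD4 0.0017 and GATAD2A 0.085, and without arrays 2 and 5 MTA3 was 0.18 and RBBP7 0.15. No paired analysis was possible, as the groups share no sample number, and 3 arrays per group limit precision. In simulated data 0% of 2-fold changes were recovered, and 31% (arrays' scaled-up residuals) or 58% (independent noise) of 4-fold changes.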

Other observations

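Of the tests below, those of exchanged labels, of the same-gene correlation and of the splits of the arrays by feature counts were chosen after the result was seen; the others were written down before.

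Gene families outside the fixed lists were screened by their shared symbol stem. Of 83 stems with at least 20 genes, 0 passed camera (lowest adjusted p = 0.726, and adjusted p = 0.953 with an estimated correlation), and 4 had an unadjusted p under 0.05. These were PRAMEF, CLEC, TAS and GAGE, and no direction is given for them, since the other scalings were not run on families.

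The first pattern is that arrays 1, 3 and 5 stand apart from arrays 2, 4 and 6, across the labels. This split was picked from the same values, so its counts restate the pattern and do not test it: 357 features at an adjusted p under 0.05 and 6661 at an unadjusted p under 0.05, against 0 and 1268 for the labelled groups. It arises if samples 2 and 5 exchange labels. MTA2 would then be 0.22 higher after its siRNA, with a lower 95% bound of -0.20, so without a 2-fold lower signal. The labels as given show no such fall either, with a difference of 0.26 and a lower bound of -0.20. MTA2 therefore cannot tell an exchange from the labels as given. No biological explanation was tested. Still open are an exchange of samples 2 and 5, batches, which the labels do not give, and the authors' normalization. Quantile normalization, after which the split called 437 features, moved a value by a median of only 0.0029 and so tested nothing. The other features of the same gene moved by 0.0273 of the called features' median shift of 1.502, in the same direction for 126 of 237, so a candidate explanation for the called features is a difference between single features, while a same-gene correlation of 0.232 among bright features leaves a gene-level part open for the others.

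The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. At an unadjusted p under 0.05, 5 of them gave at least as many features as the labels, with 1268 for the labels and at most 6661 for another split. At an adjusted p under 0.05 the labels gave 0 features and another split at most 357, and for gene lists both values were 0. Against a count of 0 all 10 splits give at least as many whatever the data, so these counts test nothing.

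The second pattern is that large folds between the labelled groups sit at the bottom of the scale. Of 148 features with a fold of at least 4, 135 have a value under 5 on at least 1 array, whereas 593 of all 34558 features do. The low values of the 148 features lie unevenly, with 89 on sample 1, 46 on sample 4, 41 on sample 3, 25 on sample 2, 23 on sample 6 and 8 on sample 5. Over all features they lie unevenly too, with 375 on sample 1, 271 on sample 4, 87 on sample 2, 80 on sample 3, 79 on sample 6 and 29 on sample 5. Samples 1 and 4 hold the most in both, so this is not particular to features with a large fold. For 86 of the 135 features, those with another feature of the same gene, the others moved by a median of 0.16 in the same direction, against 2.54 for the features themselves. In 56 of the 86 (65.1%) the others went the same way. The size is consistent with drop-outs of single features for most of the change, while the shared direction leaves a smaller change of the whole gene open, as it does changes of single transcripts. The EIF4E feature with a fitted difference of 5.92 belongs to this set, and its 2 partners differed by 2.89 and 0.73. Both partners also have a value under 5, so they cannot tell a drop-out from a change of the whole gene.

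The third pattern is that features of one gene agreed best under the labels. Across 7426 genes, which are not independent replicates, the log2 differences of a gene's 2 brightest features correlated at 0.188 for the labelled groups, against at most 0.166 for the other 9 splits. With both features above the median intensity the values were 0.271 and at most 0.232, over 3497 genes, the latter for the split of samples 1, 3 and 5 against 2, 4 and 6. A hypothesis is that the labels carry gene-level differences that are too small for the test per feature. With 10 splits the labelled one ranks highest by chance in 10% of cases, so the data cannot settle it.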
